A study of Mus musculus with 12 samples.

How the data were processed

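Polyadenylated RNA was measured by bulk RNA sequencing in primary hepatocytes of female mice, which are liver cells taken from the animal and kept in short-term culture. Per the labels' protocols, cells attached for 4 h and were infected for 42 h with an adenovirus. The virus carried a short hairpin RNA (shRNA) with a scrambled sequence or an shRNA against Ar, the gene of the androgen receptor. After 2 h without serum, with 100 nM dexamethasone, cells received vehicle or 100 nM glucagon for 8 h. The sample titles give 0 h for the vehicle samples with Ar shRNA, where the protocol text gives 8 h for every group. How long these samples were treated is therefore open, and every comparison that uses them carries that limit. Libraries were made from 3 µg of RNA by poly-T selection with a NEBNext Ultra kit, per the labels' protocols, which do not state a strand setting.

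The deposited table held estimated counts per gene, which the authors made with kallisto 0.46.0, per the submitters' processing notes. Those notes also name bcl2fastq and the GRCm38 genome build. The annotation release, the way transcripts were summed to genes and any filter on genes were not given in the sources used here. The table had 36144 gene rows and 12 libraries, no column was left unused, and 23.9% of the values were not whole numbers. In 12593 rows no library had a count. Spreadsheet software had turned 26 gene symbols into dates, and 4 of these rows shared a name with another. Together they held 0.153% of all counts, stayed in the library sizes and tests, and are not named. GENCODE release M21, which is on GRCm38, held 35907 of the 36144 symbols and gave coordinates for 319 of the 321 named genes. Pseudoalignment divides reads between near-identical genes, so values for Sult2a1 and Sult2a2, Ifit3 and Ifit3b, the Oas1, Gbp, Mup, Cyp2c and Cyp3a families, Acot1 and Acot3 and the Serpina1 genes are uncertain. Overlapping and antisense genes are uncertain as well.

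Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. The filterByExpr function kept 14415 genes, which held 99.94% of the counts. Libraries were scaled by trimmed mean of M-values (TMM), and values per library are given as CPM, counts scaled by 1e6 over the scaled library size. All 12 libraries entered a single quasi-likelihood fit with 4 groups and no other covariate. The 4 comparisons of a pair of groups and the difference of the glucagon effects were 2-sided contrasts of this fit. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05, with no limit on the fold change. Every adjusted p of a single gene comes from this edgeR quasi-likelihood test unless another tool is named. Log2 fold changes are given ± SE and CPM as mean ± SD, n = 3 per group.

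The comparisons, 29 gene lists, the alternatives and the rule for named genes were written before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 28 lists that had at least 5 tested members, and again with an estimated correlation. Named were Ar and 9 other genes chosen in advance, and in each comparison of a pair of groups the 10 largest rises and the 10 largest falls among called genes. Those genes needed a mean of at least 5 CPM in 1 of the groups, no overlap between the groups and an assigned symbol that is not a predicted-gene name. For the difference of the glucagon effects the rule took the 5 smallest p-values in each direction. Up to 4 members of each list were named by smallest p. The response to glucagon was compared between the shRNAs over genes with an average glucagon effect of at least 2-fold and an adjusted p under 0.05, using fry (limma), which tests whether a set moves on balance in 1 direction, with adjustment over the 2 sets. A group with no count of a gene was set to a floor of 3 counts over its 3 libraries, and ratios over a group with 1 to 3 counts carry a 95% exact binomial interval. Such intervals and floors cover counting error only.

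The labels do not say that replicates came from separate animals or cultures, so single-gene and fry p-values measure the spread between these samples only, which may be technical. Camera p-values at the preset correlation rest mostly on genes as replicates, not on libraries. Replicates differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 9.23 to 35.4. Pairing by replicate number was checked through the correlation, across genes, of the deviations from the group means. For glucagon with Ar shRNA the numbers paired the samples (r = 0.35, 0.30 and 0.28, with a threshold of 0.1 for every pair), and 6 of 6 samples correlated best with their own number. The labels do not say what a shared number marks. Blocked values stand beside that comparison where the block changed a call or moved a count of calls by over 1.5 times.

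On simulated counts over 14415 genes, glucagon with scrambled shRNA recovered 56.7% of 67 genes changed 1.5-fold, 88.1% of 67 changed 2-fold and 97% of 66 changed 4-fold. Glucagon with Ar shRNA recovered 70.1%, 95.5% and 98.5%. Ar shRNA without glucagon recovered 76.1%, 92.5% and 97%, and with glucagon 67.2%, 94% and 98.5%. The difference of the glucagon effects recovered 37.3%, 76.1% and 95.5%. False calls made up 8%, 4.86%, 7.33%, 4.42% and 6.08% of the calls in these 5 simulations. Few genes were changed and recovery was not split by count. These rates need not hold at low counts or where many genes change.

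Alternatives were DESeq2 size factors, no filter on low counts, unrounded counts, a replicate block, only the groups compared, each library left out in turn, the DESeq2 1.42.0 Wald test, lists tested with an estimated correlation, and response sets chosen on either shRNA arm alone. Robust empirical Bayes, a replicate block with only the groups compared, and a fit without the scrambled library lowest in mitochondrial transcripts in each treatment were added after the data were seen.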

Results

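Messenger RNA was measured in 12 libraries of primary hepatocytes from female mice, in 4 groups of 3: scrambled shRNA with vehicle, scrambled shRNA with glucagon, Ar shRNA with vehicle, and Ar shRNA with glucagon. The study concerns the androgen receptor and the response of female liver cells to glucagon, the fasting hormone that turns on glucose output, with Ppargc1a, the nuclear receptor Esrra and mitochondria as its focus. Total counts were 22194705, 20005461 and 21575342 with scrambled shRNA and vehicle, and 22854326, 22197932 and 19631939 with scrambled shRNA and glucagon. With Ar shRNA they were 20545296, 19472575 and 23255029 on vehicle and 20418532, 18985508 and 21251116 on glucagon. The shRNA separated the libraries along a first principal component that held 69% of the variance, and the next held 9.36%. Genes named only to complete a count of 5 or fewer were chosen after their values were seen.

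Ar was lower in each of the 6 libraries with Ar shRNA than in any of the 6 with scrambled shRNA. This gene, which encodes the androgen receptor, a steroid-activated transcription factor, lies on chromosome X at 98148769 to 98323215 of GRCm38 (ENSMUSG00000046532, plus strand, protein-coding). Its counts in replicates 1 to 3 were 97, 143 and 194 with scrambled shRNA and vehicle and 143, 176 and 172 with scrambled shRNA and glucagon. Ar shRNA gave 16, 25 and 41 counts on vehicle and 9, 35 and 37 on glucagon. The group means were 6.76 ± 2.39, 8.02 ± 1.38, 1.25 ± 0.477 and 1.32 ± 0.759 CPM (SD, n = 3). Ar shRNA lowered Ar by 5.35-fold without glucagon (log2 fold change −2.42 ± 0.42, SE, adjusted p = 3.01e-04) and by 6.04-fold with glucagon (−2.59 ± 0.42, adjusted p = 1.42e-04). Glucagon left Ar without a call in both arms, at 0.25 with scrambled shRNA (adjusted p = 0.696) and 0.07 with Ar shRNA (adjusted p = 0.975).

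**Figure D1:**
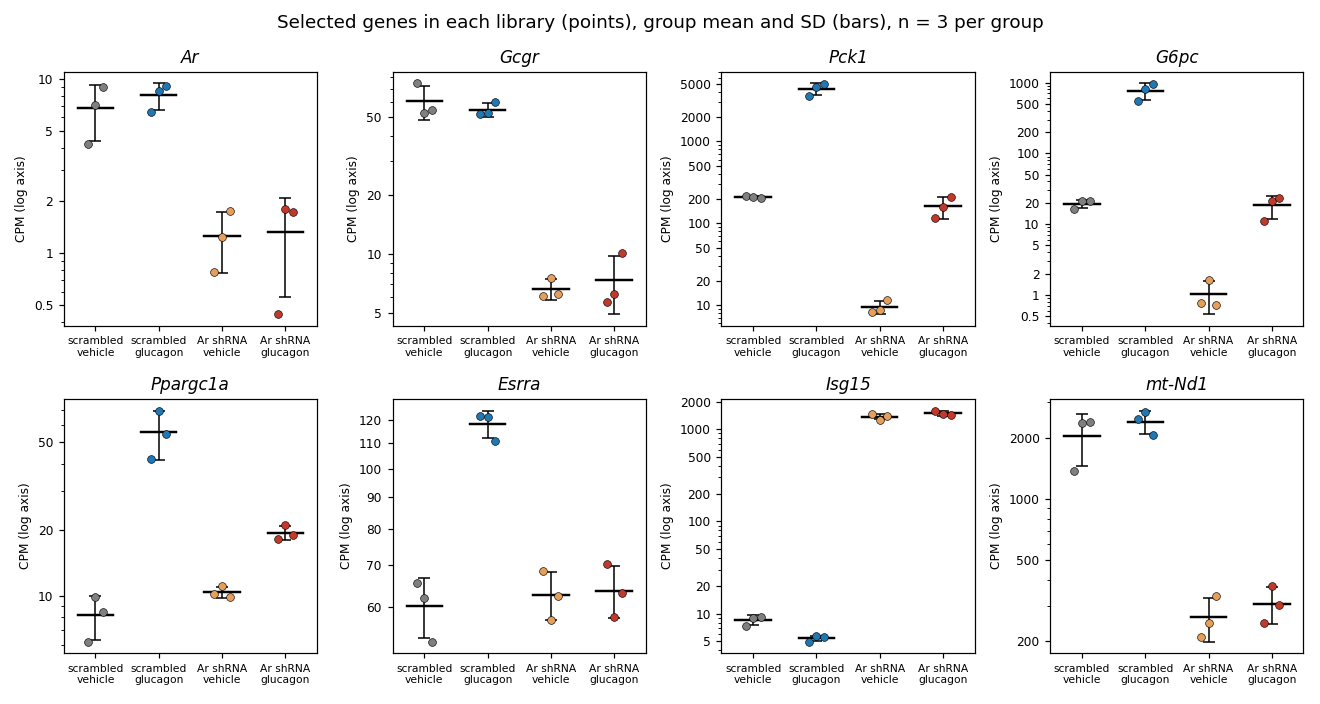
Expression in CPM (log axis) of Ar, Gcgr, Pck1, G6pc, Ppargc1a, Esrra, Isg15 and mt-Nd1 in the 4 groups; each point is 1 library and the bars are the group mean ± SD, n = 3. Mean Pck1 went from 210 to 4390 CPM with glucagon in scrambled cells and from 9.53 to 161 CPM in Ar shRNA cells.

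With scrambled shRNA, glucagon raised Pck1, the enzyme that commits carbon to gluconeogenesis, by 20.9-fold, from 210 ± 6.35 to 4390 ± 697 CPM (SD, n = 3; log2 4.39 ± 0.21, adjusted p = 1.09e-08). G6pc, which releases free glucose, rose 39.4-fold from 19.5 ± 2.57 to 768 ± 204 CPM (5.30 ± 0.29). Ppargc1a, the coactivator of mitochondrial and gluconeogenic genes, rose 6.78-fold from 8.18 ± 1.85 to 55.4 ± 13.9 CPM (2.76 ± 0.19, adjusted p = 3.03e-07), and its partner Esrra rose 1.97-fold (0.98 ± 0.10, adjusted p = 8.66e-06). The largest rises also held Adra2a, an adrenergic receptor (808-fold), Pah, which hydroxylates phenylalanine (49.0-fold), Cyp17a1, a steroid hydroxylase (32.0-fold), and Mat1a, which makes S-adenosylmethionine (23.1-fold). Akr1b7 rose by 5.80 on the log2 scale, Etnppl by 5.32 and the leptin receptor Lepr by 5.06. The neuronal transcription factor Ascl1 had 2 counts over the 3 vehicle libraries and 545 over the 3 glucagon libraries, a ratio of 286 (95% counting interval 78.8 to 2370). The largest falls were those of Rad51b at −3.25, Dsg1c at −2.62, Fjx1 at −2.61, Nrk at −2.47, Cish at −2.39, Ivl at −2.24, Mlph at −2.23, Prph at −2.20, and the interferon-inducible genes Tgtp1 at −2.05 and Gvin1 at −1.96. Tat, which degrades tyrosine, rose 9.77-fold, Cpt1a, which admits fatty acids to mitochondria, rose 3.18-fold, and Fkbp5 fell (−0.62, adjusted p = 5.77e-04). Gcgr, the glucagon receptor, stood at −0.15 (adjusted p = 0.595) and the ketogenic enzyme Hmgcs2 at 0.01 (adjusted p = 0.99).

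Across 14415 tested genes, 1929 rose and 1648 fell with glucagon in scrambled cells, 3577 in all (24.8%). Of these, 414 and 304 changed at least 2-fold. Leaving out 1 library ended the call of Ivl, with adjusted p = 0.188 without scrambled vehicle replicate 3, 0.113 without glucagon replicate 1 and 0.132 without glucagon replicate 2. Pck1 lies at chromosome 2, 173153048 to 173159273, G6pc at chromosome 11, 101367561 to 101377903, Ppargc1a at chromosome 5, 51454250 to 51567726, Esrra at chromosome 19, 6910977 to 6921813, and Gcgr at chromosome 11, 120530699 to 120538986, all protein-coding genes on GRCm38.

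In scrambled cells 34 of 38 genes of amino acid catabolism and the urea cycle rose and none fell (35 adjusted over the list alone), with a median of 3.19-fold and a camera adjusted p of 4.1e-98. Oat, which converts ornithine, rose 15.0-fold, the aminotransferase Got1 14.8-fold and the ornithine carrier Slc25a15 12.5-fold. In the list for gluconeogenesis and pyruvate handling 18 of 24 rose and none fell (20 adjusted over the list alone), with a camera adjusted p of 3e-24; Fbp1 rose 8.50-fold and the ATP-magnesium carrier Slc25a25 rose by 2.83 on the log2 scale. Of 32 genes induced by cAMP and CREB, the messenger and transcription factor downstream of the receptor, 21 rose, and Junb (−0.94), Gadd45b (−1.64) and Cited2 (−0.71) fell (22 and 4 adjusted over the list alone; camera adjusted p = 1.1e-20); the arginine carrier Slc7a2 rose by 2.71. In glucagon receptor signalling and glycogen 13 of 35 rose (15 adjusted over the list alone), among them the phosphodiesterases Pde4b (1.79) and Pde3b (1.31) and the glycogen targeting subunit Ppp1r3c (2.19), and Phka2 (−0.35) and Arrb1 (−0.56) fell, 3 adjusted over the list alone (camera adjusted p = 3.6e-05). These 4 lists also kept their call with an estimated correlation, and no other list did in this comparison.

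In the tricarboxylic acid cycle 12 of 22 genes rose with glucagon in scrambled cells and none fell (13 adjusted over the list alone), with Fh1 up 4.70-fold and Idh3a 2.07-fold. Here camera gave adjusted p = 3e-08, or 0.057 with an estimated correlation. Nuclear-encoded oxidative phosphorylation had 24 of 77 higher and none lower (24 adjusted over the list alone) at a median of 0.17, with the succinate dehydrogenase subunits Sdhd (0.60) and Sdhb (0.53) in front. Camera testing gave adjusted p = 6.4e-04, or 0.42 with an estimated correlation. None of the 13 mitochondrially encoded messenger RNAs passed (median 0.20, camera adjusted p = 0.50). Their median was −0.06 without scrambled vehicle replicate 1, the library with 1.62% mitochondrial counts against 3.21% and 3.18% in replicates 2 and 3. Fatty acid oxidation and ketogenesis had 16 of 32 higher and 4 lower (20 and 5 adjusted over the list alone); Acsl1 rose by 1.88, Ehhadh by 1.46 and Acox1 by 1.13, and Hadh (−0.26), Bdh1 (−0.77), Acat1 (−0.50) and Vnn1 (−0.70) fell. With camera this gave adjusted p = 5.4e-06, or 0.33 with an estimated correlation. Among the PGC1 and ERR regulators 7 of 25 rose, with the deacetylase Sirt3 at 0.89 and the fusion protein Mfn2 at 0.43, and Pprc1 fell (−0.37), the same counts adjusted over the list alone. Camera here gave adjusted p = 0.020, or 0.45 with an estimated correlation.

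Of cytoskeletal and dedifferentiation genes, which climb in hepatocyte culture, 25 of 33 fell with glucagon in scrambled cells (27 adjusted over the list alone), including Vim at −1.57, Ccn2 at −1.68 and Ccn1 at −1.14, and Tubb2a (0.56) and Afp (2.48) rose. The camera test gave adjusted p = 5.9e-13, or 0.13 with an estimated correlation. The interferon list had 21 of 40 lower (23 adjusted over the list alone), with Ifit3 at −1.32, Rtp4 at −1.18 and Ifi47 at −1.07, and Usp18 rose (0.89). Here camera gave adjusted p = 2.4e-06, or 0.34 with an estimated correlation. NRF2 targets, the antioxidant genes, had 13 of 29 lower (15 adjusted over the list alone), with Hmox1 at −1.01 and Gsta1 at −1.24, and Ugdh rose (0.33). Camera then gave adjusted p = 6.4e-04, or 0.18 with an estimated correlation. Cholesterol synthesis had 13 of 26 lower (16 adjusted over the list alone), with Insig1 at −1.09 and Hmgcs1 at −0.91, and Lss, Ebp, Hsd17b7 and Pmvk rose. Camera testing gave adjusted p = 0.0074, or 0.39 with an estimated correlation. The p53 targets had 13 of 24 lower (14 adjusted over the list alone), with Plk2 at −0.84, and Plk3 (1.23), Ei24 (0.94) and Trp53inp1 (0.23) rose. By camera this gave adjusted p = 0.048, or 0.57 with an estimated correlation. That call ended without scrambled vehicle replicate 1 (0.123), glucagon replicate 1 (0.0626), glucagon replicate 2 (0.123) or glucagon replicate 3 (0.0687), and without the scrambled libraries lowest in mitochondrial transcripts (0.139). Of 33 cell cycle genes Ccnd1 (−1.50) and Mcm7 (−0.47) fell (1 adjusted over the list alone; camera adjusted p = 0.0077; adjusted p = 0.67 with an estimated correlation), and the list's call ended without glucagon replicate 1 (0.0576). Mcm7 lost its own call without vehicle replicates 1 (0.0882) or 2 (0.0513) or glucagon replicates 2 (0.0843) or 3 (0.0585). The acute phase list had 8 of 29 lower (9 adjusted over the list alone), with Hp at −0.72 and Steap4 at −1.39, and Socs3, Il6ra and Stat3 rose (camera adjusted p = 0.020; adjusted p = 0.36 with an estimated correlation); its call ended without glucagon replicate 1 (0.0622).

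Androgen-responsive genes had 8 of 22 higher and 5 lower in scrambled cells (9 and 5 adjusted over the list alone), with the kinase Sgk1 at 2.69 and the prostaglandin enzyme Hpgd at 1.57. Camera gave adjusted p = 0.024, and adjusted p = 0.13 with an estimated correlation. The call ended without scrambled vehicle replicate 2 (0.0505) and with no filter on low counts (0.112). Female-biased liver genes had 8 of 26 higher (10 adjusted over the list alone), and Abcd2 fell (−2.85). Camera then gave adjusted p = 0.0099, and adjusted p = 0.42 with an estimated correlation. Cholangiocyte markers, those of bile duct cells, had 5 of 9 lower, also adjusted over the list alone, including Sox9 at −1.30 and Cldn4 at −1.16. Krt19, also among the 5, lost its call without vehicle replicates 2 (0.0709) or 3 (0.103) or glucagon replicate 1 (0.0824). For cholangiocyte markers, camera gave adjusted p = 0.0072, and adjusted p = 0.42 with an estimated correlation. No camera call was made for the male-biased list (2 higher and 5 lower of 19, adjusted p = 0.51), fatty acid synthesis (6 and 6 of 24, with Gck at −1.81, 0.69), stress response (3 and 4 of 34, 0.87, median −0.05 and mean 0.04), drug and bile acid metabolism (7 and 6 of 35, with Cyp8b1 at 3.12, 0.90), circadian clock (7 and 5 of 21, with Arntl at 1.05, 0.50) or hepatocyte identity (8 and 4 of 33, with Hnf4a at 0.72, 0.24). The same held for Kupffer cell markers (Cd14 fell, −0.85, of 18, 0.41), endothelial markers (none of 18, 0.98) and stellate markers (Ecm1 at −0.43 of 17, 0.85, median 0.09 against a downward test). Adjusted over the list alone, rises and falls became 3 and 5 for the male-biased list, 8 and 7 for fatty acid synthesis, 8 and 6 for drug and bile acid metabolism, 8 and 6 for the clock, 9 and 4 for hepatocyte identity and 0 and 0 for stellate markers. Ecm1 lost its call without scrambled vehicle replicate 3 (0.128) or glucagon replicates 1 (0.0627) or 2 (0.0981). Lymphocyte markers had 4 tested members, too few for a list test, and Cd8a rose (1.33), a call that ended without any 1 of the 6 libraries (0.0975, 0.0881 and 0.0622 for vehicle replicates 1 to 3, and 0.0567, 0.098 and 0.0627 for glucagon).

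With Ar shRNA, glucagon still raised Pck1 16.9-fold, from 9.53 to 161 CPM (log2 4.08 ± 0.21, n = 3, adjusted p = 9.9e-08), and G6pc 17.9-fold, from 1.04 to 18.5 CPM (4.17 ± 0.37, adjusted p = 2.33e-05). Ppargc1a rose 1.86-fold, from 10.4 to 19.4 CPM (0.90 ± 0.18, adjusted p = 0.014), and Esrra stood at 62.7 and 63.7 CPM (0.02, adjusted p = 0.962). Adra2a rose 81.2-fold, Arg1, the last enzyme of the urea cycle, 35.6-fold, Mat1a 19.3-fold and Pah 10.9-fold. Other large rises were of the chemokine receptor Ackr3 (3.82), the alcohol dehydrogenase Adh1 (3.68), the calcium channel Cacna1c (3.48) and Slc25a15 (3.05). The largest falls were those of Mlph at −1.41, the integrin Itga2 at −1.37, Plekhs1 at −1.29, Fjx1 at −1.25, Emp1 at −1.17, the sphingosine kinase Sphk1 at −1.16, Itgb6 at −1.16, Fam81a at −1.13, Adamtsl4 at −1.07 and Steap4 at −1.02. Tat rose (2.14) and Cpt1a rose (1.11), and no call was made for Gcgr (0.16, adjusted p = 0.836), Hmgcs2 (−0.29, 0.838) or Fkbp5 (−0.18, 0.482; 0.0201 in the blocked fit of these 6 libraries). Ppargc1a lost its call without Ar shRNA vehicle replicate 1 (0.0531), vehicle replicate 3 (0.0688) or glucagon replicate 2 (0.0576). Among the falls, calls ended for Mlph without vehicle replicates 2 (0.0864) or 3 (0.091) or glucagon replicates 1 (0.101), 2 (0.0536) or 3 (0.0754), and for Itga2 without vehicle replicates 1 (0.0669) or 3 (0.167) or glucagon replicates 1 (0.145), 2 (0.0857) or 3 (0.0803). The call of Plekhs1 ended without vehicle replicates 2 (0.0963) or 3 (0.113) or glucagon replicates 1 (0.114), 2 (0.105) or 3 (0.093), and that of Fjx1 without vehicle replicates 1 (0.0873) or 3 (0.126) or glucagon replicates 1 (0.0714), 2 (0.128) or 3 (0.0861). Emp1 was lost without vehicle replicate 3 (0.0737) or glucagon replicates 1 (0.062) or 3 (0.0774), Itgb6 without vehicle replicate 3 (0.0585) or glucagon replicates 2 (0.055) or 3 (0.0638), and Fam81a without vehicle replicate 3 (0.0805) or glucagon replicates 1 (0.0754) or 3 (0.0892).

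Glucagon changed 545 genes with Ar shRNA (3.78% of 14415), 362 higher and 183 lower, of which 109 and 19 changed at least 2-fold (490 higher and 289 lower by the DESeq2 Wald test). With a replicate block the count was 895, and 2075 with the block and only these 6 libraries, a fit added after the data were seen. The count fell to 359 without vehicle replicate 1, 294 without vehicle replicate 3, 350, 351 and 288 without glucagon replicates 1, 2 and 3, and was 394 without vehicle replicate 2.

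Amino acid catabolism had 17 of 38 genes higher with glucagon in Ar shRNA cells and none lower (21 adjusted over the list alone; median 0.34, camera adjusted p = 5.5e-88). The cAMP and CREB list had 16 of 32 higher (18 adjusted over the list alone), with Slc7a2 up 5.32-fold and Pde4b at 1.32 (camera adjusted p = 2.9e-33), and Creb3l3 fell (−0.48). Creb3l3 lost its call without vehicle replicates 1 (0.136) or 3 (0.184) or glucagon replicates 1 (0.188), 2 (0.0611) or 3 (0.119). Gluconeogenesis had 7 of 24 higher and none lower (10 adjusted over the list alone), with Got1 up 3.02-fold and Gpt2 by 1.38 (camera adjusted p = 3.1e-20). Circadian clock genes had 7 of 21 higher (8 adjusted over the list alone), with the repressors Per2 (0.61), Cry2 (0.63) and Nfil3 (0.51), and Bhlhe40 fell (−0.46; camera adjusted p = 2.8e-04). In glucagon receptor signalling, Pde3b, Pde4b, Pde4d, Rapgef4 and Ppp1r3c rose of 35 (8 higher and 3 lower adjusted over the list alone; camera adjusted p = 2.8e-04). These 5 lists kept their call with an estimated correlation and no other did. The tricarboxylic acid cycle list had Fh1 (1.18) and Pdhb (0.29) higher of 22, 3 adjusted over the list alone (camera adjusted p = 0.0076; adjusted p = 0.43 with an estimated correlation); its call ended without vehicle replicate 3 (0.0561). Pdhb was lost without vehicle replicates 1 (0.0873), 2 (0.0597) or 3 (0.174) or glucagon replicates 1 (0.155), 2 (0.116) or 3 (0.0792). Dedifferentiation genes had 4 of 33 lower (7 adjusted over the list alone), with Vim at −0.82, and Tubb2a (0.62) and Afp (2.35) higher (camera adjusted p = 0.013; adjusted p = 0.84 with an estimated correlation; 0.197 with a replicate block). Of 9 cholangiocyte markers Pkhd1 fell (−0.43). Camera here gave adjusted p = 0.026, and adjusted p = 0.80 with an estimated correlation. The call of that list ended without vehicle replicates 2 (0.277) or 3 (0.0561) or glucagon replicates 1 (0.427) or 3 (0.0633), and with no filter on low counts (0.119). Pkhd1 was lost without vehicle replicates 1 (0.174), 2 (0.0538) or 3 (0.0934) or glucagon replicates 1 (0.109), 2 (0.136) or 3 (0.146).

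With a replicate block over all 12 libraries, rises and falls numbered 20 and 0 for amino acid catabolism, 18 and 1 for the cAMP list, 10 and 0 for gluconeogenesis, 7 and 3 for glucagon receptor signalling, 2 and 6 for dedifferentiation, and 0 and 2 for cholangiocyte markers, where Krt7 joined Pkhd1. Idh3a (0.24) and Ogdh (0.23) joined Fh1 and Pdhb. With the block and only these 6 libraries they numbered 26 and 0 of 38 for amino acid catabolism, 20 and 4 of 32 for the cAMP list and 11 and 1 of 24 for gluconeogenesis. They were 11 and 3 of 20 for the clock and 10 and 3 of 34 for glucagon receptor signalling. The tricarboxylic acid cycle had 6 and 0 of 22, dedifferentiation 6 and 18 of 33 (camera adjusted p = 0.056) and cholangiocyte markers 0 and 6 of 9. With an estimated correlation, the calls of the first 5 of these lists held with the block over 12 libraries. They ended in the fit of 6, at adjusted p = 0.090 with an estimated correlation for amino acid catabolism, the cAMP list and gluconeogenesis, 0.35 for the clock and 0.28 for glucagon receptor signalling.

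No camera call was made in Ar shRNA cells for the remaining lists. Oxidative phosphorylation had none of 77 genes past the test (median 0.01, adjusted p = 0.81), mitochondrially encoded RNAs none of 13 (0.27, 0.16), the p53 targets none of 24 (0.81), the stress response none of 34 (0.81), male-biased genes none of 19 (0.81), Kupffer markers none of 18 (0.81) and stellate markers none of 17 (0.54). With a replicate block over all 12 libraries Cdkn1a and Gdf15 rose and Perp fell among the p53 targets, and Gdf15 rose in the stress response. With the block and only these 6 libraries, Ndufa6 (0.36, adjusted p = 9.42e-04), Atp5b (0.14, adjusted p = 0.0215), Cycs and Cox8a rose in oxidative phosphorylation. In that fit mt-Nd4, mt-Nd5 (0.46, adjusted p = 0.0297), mt-Nd6 (0.19, adjusted p = 0.0221) and mt-Co1 (0.29, adjusted p = 0.0425) rose, and the mitochondrially encoded list gained a camera call (adjusted p = 0.020; adjusted p = 0.88 with an estimated correlation). It also gave 5 rises and 6 falls of 24 for the p53 targets, 6 and 5 of 34 for the stress response, and 0 and 1 of 15 for stellate markers (Ecm1, −0.31). Fatty acid oxidation had Cpt1a, Acsl1 (0.95) and Acox1 (0.67) higher and 1 gene lower of 32 (adjusted p = 0.74, median −0.05 and mean 0.01). Single genes rose in the PGC1 and ERR list (Ppargc1a of 25, 0.81), fatty acid synthesis (Gpam of 24, 0.74), interferon (Irf9 of 40, 0.16), hepatocyte identity (Prox1 of 33, 0.26) and endothelial markers (Stab2 of 18, 0.70), and Ccnd1 fell in the cell cycle list (of 33, 0.19). Irf9 was lost without vehicle replicates 1 (0.0773), 2 (0.0694) or 3 (0.0669) or glucagon replicates 1 (0.0598) or 2 (0.0957), and Prox1 without vehicle replicates 1 (0.0531) or 3 (0.0673) or glucagon replicate 3 (0.0662). Stab2 was lost without vehicle replicates 1 (0.154) or 2 (0.155) or glucagon replicates 1 (0.0804), 2 (0.112) or 3 (0.16). Ccnd1 was lost without vehicle replicates 2 (0.123) or 3 (0.127) or glucagon replicates 1 (0.136), 2 (0.0668) or 3 (0.112). Counts of rises and falls were 2 and 1 of 26 in cholesterol synthesis (0.81), 2 and 0 of 29 for NRF2 targets (0.81), 2 and 2 of 35 in drug and bile acid metabolism (0.22) and 2 and 1 of 29 in the acute phase list (Socs3 at 1.45, 0.63). Adjusted over the list alone they became 3 and 1, 2 and 1, 4 and 2, and 3 and 1. Fatty acid oxidation had 3 and 2 in that way, the PGC1 and ERR list 1 and 1, interferon 2 and 0 and the androgen-responsive list 4 and 2. With a replicate block, camera calls were gained for the androgen-responsive list (3 and 2 of 22, adjusted p = 0.080 without and 0.0122 with the block), the female-biased list (4 and 0 of 26, 0.080 and 0.00518, median −0.07 against an upward test) and the cell cycle list (0.00685). With an estimated correlation those blocked tests gave adjusted p = 0.093, 0.25 and 0.73. In the blocked fit of the 6 libraries the same lists passed (0.0241, 0.00703 and 0.00703), at adjusted p = 0.35, 0.35 and 0.81 with an estimated correlation, with 8 and 4, 7 and 1, and 0 and 5 genes called. Further counts of rises and falls in that fit were 3 and 4 in fatty acid oxidation, 2 and 3 for PGC1 and ERR regulators, 2 and 3 in fatty acid synthesis, 3 and 4 in cholesterol synthesis, 4 and 0 for interferon, 4 and 3 for NRF2 targets and 6 and 4 in drug and bile acid metabolism. They were 7 and 4 in the acute phase list, 2 and 1 for hepatocyte identity and 1 and 2 for endothelial markers. With the block over 12 libraries, 1 gene was gained in each of fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, interferon, NRF2 targets, the acute phase list, hepatocyte identity and the androgen-responsive list, 2 in drug and bile acid metabolism and 3 in the female-biased list. Median and mean differed in sign for the p53 targets, where the test pointed down, for male-biased genes (0.01 and −0.07, tested down) and for the acute phase list (−0.03 and 0.06, tested up). None of the 4 lymphocyte markers passed.

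In Ar shRNA against scrambled cells without glucagon, Ifit3, which encodes an antiviral protein, went from 4.22 to 2939 CPM, 698-fold (log2 9.45 ± 0.15, n = 3, adjusted p = 7.41e-14), and the chemokine Ccl5 rose 3957-fold (11.95 ± 0.28). Other large rises were those of Gbp10 (10.64), Acod1, which makes itaconate (10.30), Ifit3b (10.17), Oas2 (9.63), the keratin Krt17 (8.89) and the chemokines Cxcl10 (8.51) and Cxcl11 (8.48). Pou3f1 had 2 counts in scrambled and 5025 in Ar shRNA libraries, a ratio of 2520 (95% counting interval 698 to 20800). The hepatic glucose kinase Gck fell 135-fold, from 130 to 0.96 CPM (−7.07 ± 0.24), Arg1 59.1-fold, from 187 to 3.16 CPM, and Hmgcs2 52.9-fold, from 657 ± 190 to 12.4 ± 3.95 CPM. Sult2a1 (−6.48), Cyp7a1, the first enzyme of bile acid synthesis (−6.48), Cyp1a2 (−6.35), Cpn2 (−6.15), Sult2a2 (−5.39), the iron regulator Hfe2 (−5.34) and Bhmt (−5.25) followed. Gcgr fell 9.16-fold, from 60.7 ± 12 to 6.63 ± 0.797 CPM (adjusted p = 1.74e-08). Pck1 (−4.46 ± 0.21), G6pc (−4.24 ± 0.37), Tat (−1.86), Fkbp5 (−0.85) and Cpt1a (−0.33) fell as well, and no call was made for Ppargc1a (0.35, adjusted p = 0.138) or Esrra (0.06, 0.629).

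Of 14415 genes, 3779 were higher and 3673 lower with Ar shRNA on vehicle, 7452 in all (51.7%), with 1143 and 1244 of them changed at least 2-fold. Mitochondrial transcripts made up 1.62%, 3.21% and 3.18% of counts in scrambled vehicle replicates 1 to 3 and 0.448%, 0.506% and 0.786% with Ar shRNA. The interferon list took 0.103% to 0.105% of counts in the former and 2.91% to 3.16% in the latter. Calls that held with an estimated correlation were interferon, fatty acid synthesis, NRF2 targets, and drug and bile acid metabolism.

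The interferon list had 39 of 40 genes higher, also adjusted over the list alone, at a median of 55.1-fold (camera adjusted p = 1.3e-218), with Oasl2 at 7.12 and Isg15, a ubiquitin-like modifier, up 160-fold. Drug and bile acid metabolism had 24 of 35 lower and Cyp2c54, Cyp4a10 and Cyp4a14 higher, unchanged adjusted over the list alone, with the bile acid conjugating enzyme Baat at −4.06 and Ugt2b5 at −2.86 (camera adjusted p = 3.8e-10). NRF2 targets had 24 of 29 lower and G6pdx (0.37) and Taldo1 (0.30) higher, the same adjusted over the list alone, with Gsta1 at −3.06 and Gsta3 at −1.74 (camera adjusted p = 7.8e-09). Fatty acid synthesis had 15 of 24 lower (15 adjusted over the list alone), with Mlxipl, the carbohydrate-response factor, at −1.99, and Thrsp (3.41), G6pdx and Srebf1 (0.31) higher (camera adjusted p = 0.0018). All 13 mitochondrially encoded RNAs fell, also adjusted over the list alone, at a median of 7.09-fold (mt-Nd1 7.70-fold, mt-Co3 −2.83, mt-Atp8 −3.20, mt-Nd6 −1.84). The camera test gave adjusted p = 5.4e-06, or 0.33 with an estimated correlation. Nuclear-encoded oxidative phosphorylation had 31 of 77 lower (31 adjusted over the list alone) at a median of −0.17, with Ndufb10 at −0.69 and Atp5g1 at −0.59, and Ndufb6, Ndufb8 and Ndufs4 rose. Here camera gave adjusted p = 0.027, or 0.62 with an estimated correlation. Fatty acid oxidation had 29 of 32 lower (29 adjusted over the list alone), with Acat1 at −1.91 and Hadh at −1.25, and Vnn1 rose (2.04). Camera testing gave adjusted p = 7.2e-10, or 0.16 with an estimated correlation. Amino acid catabolism had 30 of 38 lower (30 adjusted over the list alone), with Uroc1 at −4.16 and Cbs at −1.97, and Got1 (0.30), Oat (0.59), Sdsl (0.43), Agxt (0.36) and Slc25a22 (0.87) rose. With camera this gave adjusted p = 6.8e-12, or 0.13 with an estimated correlation. Gluconeogenesis had 14 of 24 lower and Gpi1, Got1 and Slc25a25 higher, the same adjusted over the list alone, with Gpt2 at −2.41. By camera this gave adjusted p = 4.6e-06, or 0.071 with an estimated correlation. The tricarboxylic acid cycle had 14 of 22 lower (14 adjusted over the list alone), with Idh2 at −1.79, and Pdhx rose (0.28). Camera here gave adjusted p = 0.0071, or 0.27 with an estimated correlation.

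Hepatocyte identity genes had 22 of 33 lower (23 adjusted over the list alone), with transferrin, Trf, at −3.83, Hnf4a at −1.16 and Hnf1a at −1.12, and Apoa2 (0.97), Asgr2 (0.93), Foxa2 (0.56) and F9 (0.33) rose. The camera test gave adjusted p = 2.5e-05, or 0.24 with an estimated correlation. Male-biased liver genes had 13 of 19 lower (13 adjusted over the list alone), with Cyp2d9 at −3.66 and Selenbp2 at −3.04, and Susd4 rose (2.28). Camera gave adjusted p = 1.9e-04, or 0.21 with an estimated correlation. Female-biased genes had 15 of 26 lower (15 adjusted over the list alone), with Cyp39a1 at −2.60, and Cyp2b9, Cyp2b13, Cyp3a16, Fmo3 and Hexb rose. Camera then gave adjusted p = 0.013, or 0.38 with an estimated correlation. The p53 targets had 17 of 24 higher (17 adjusted over the list alone), with Btg2 at 1.97, Fas at 1.42 and Mdm2 at 0.94, and Gdf15 fell (−0.37). By camera this gave adjusted p = 1.7e-04, or 0.27 with an estimated correlation. Without a camera call, rises and falls numbered 12 and 11 of 32 in the cAMP list (Atf3 at 1.79, Creb3l3 at −2.85; adjusted p = 0.45, median 0.19, mean −0.25), 5 and 6 of 25 in the PGC1 and ERR list (Sirt3 at −1.27; 0.53, median −0.04, mean 0.02) and 11 and 16 of 35 in glucagon receptor signalling (Rapgef4 at −3.17, Pygl at −1.18; 0.070). They numbered 5 and 12 of 22 for androgen-responsive genes (Sord at −2.15, Azgp1 at −1.88, Sgk1 at 1.34; 0.070), 2 and 14 of 26 in cholesterol synthesis (Dhcr24 at −1.97; 0.066), 18 and 10 of 34 in the stress response (Ddit3 at 2.59, Creld2 at 2.36; 0.27), 7 and 12 of 29 in the acute phase list (Il1rn at 5.47, Fgg at −2.58; 0.067), 6 and 8 of 21 for the clock (Per1 at 0.81, Per3 at −1.43; 0.82), 1 and 4 of 33 for the cell cycle (Mcm6 at 0.69, Cdk2 at −0.64; 0.43) and 16 and 8 of 33 for dedifferentiation (Lgals3 at 1.59, Sox4 at −2.10; 0.61). Markers of other liver cells had 5 higher and 7 lower of 18 for Kupffer cells (Cybb at 2.58, Cd68 at 2.04, Lyz2 at −3.32; adjusted p = 0.82), 2 and 8 of 18 for endothelium (Flt4 at 3.39, Stab2 at −2.36; 0.27), 2 and 1 of 17 for stellate cells (Tagln at 1.05, Reln at −1.42; 0.89) and 2 and 2 of 9 for cholangiocytes (Cldn4 at 1.91; 0.89). Of the 4 lymphocyte markers Ccl5 rose, and Lck had 3 counts in scrambled against 33 in Ar shRNA libraries, a ratio of 11.1 (95% counting interval 3.47 to 56.3), whose call ended without Ar shRNA vehicle replicate 2 (0.0549). Among cholangiocyte markers Krt19 lost its call without scrambled vehicle replicates 1 (0.13) or 2 (0.0652), Ar shRNA vehicle replicates 1 (0.0523) or 2 (0.164), and with the DESeq2 Wald test (0.0768). Tspan8 lost it without scrambled vehicle replicates 2 (0.101) or 3 (0.121), Ar shRNA vehicle replicates 1 (0.11) or 2 (0.0603), and with the DESeq2 Wald test (0.0661). Pkhd1 lost it without scrambled vehicle replicate 3 (0.201), Ar shRNA vehicle replicates 2 (0.142) or 3 (0.112), and with no filter on low counts (0.0762). Among cell cycle genes, Mcm4 lost its call without scrambled vehicle replicate 1 (0.0973) or Ar shRNA vehicle replicates 1 (0.0959) or 3 (0.0544), and Tk1 without scrambled vehicle replicate 2 (0.0881) or Ar shRNA vehicle replicate 1 (0.0923). Adjusted over the list alone, rises and falls became 1 and 1 for the cell cycle, 3 and 14 for cholesterol synthesis, 11 and 17 for glucagon receptor signalling and 5 and 8 for Kupffer markers.

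**Figure D2:**
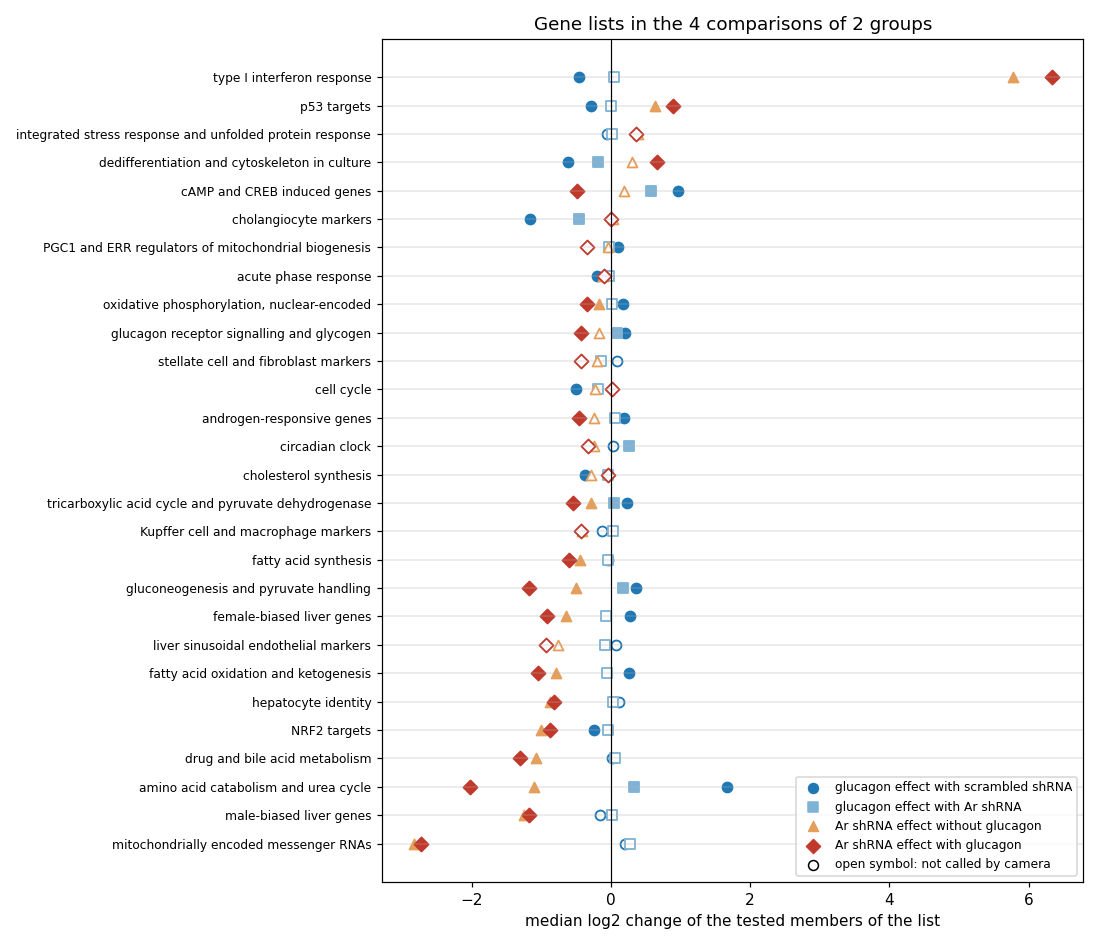
Median log2 fold change (horizontal axis) of the 28 tested gene lists (vertical axis) in the 4 comparisons of a pair of groups; filled symbols are lists called by camera and open symbols are not, n = 3 per group. The interferon list stood at 5.78 and 6.33 with Ar shRNA, and the mitochondrially encoded RNAs at −2.83 and −2.73.

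With glucagon present, Pck1 fell with Ar shRNA by 27.2-fold, from 4390 to 161 CPM (log2 −4.77 ± 0.21, n = 3, adjusted p = 4.16e-10), G6pc 41.5-fold, from 768 to 18.5 CPM (−5.37 ± 0.29), Ppargc1a 2.85-fold, from 55.4 to 19.4 CPM (−1.51 ± 0.18), Esrra 1.86-fold (−0.89 ± 0.10) and Gcgr 7.42-fold (−2.89 ± 0.20). Cpt1a (−0.89), Fkbp5 (−0.41) and Hmgcs2 (−6.03) also fell, and Tat fell 8.02-fold. Further large falls were those of Cpn2 (−6.29), Cyp7a1 (−6.26), Gck (−6.00), Cyp1a2 (−5.49), Hfe2 (−5.43), Akr1c6 (−5.29), the histidine pathway enzyme Uroc1 (−5.25) and the carboxylate carrier Slc13a3 (−5.21). Large rises were of Ccl5 (12.39), Ifit3b (11.87), Ifit3 (10.80), Acod1 (9.96), Pou3f1 (9.50), Oas2 (9.07), Oas3 (8.86), Ifit1 (8.83) and Gbp3 (8.55). Gbp10 had 0 counts in scrambled and 18806 in Ar shRNA libraries, at least 6320-fold higher. In all, 3996 genes were higher and 4149 lower, 8145 or 56.5% of 14415, with 1308 and 1548 of them changed at least 2-fold. Mitochondrial transcripts were 3.07%, 3.38% and 2.22% of counts in scrambled glucagon replicates 1 to 3 and 0.579%, 0.820% and 0.708% with Ar shRNA.

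All 38 amino acid catabolism genes fell with Ar shRNA under glucagon, also adjusted over the list alone, at a median of 4.05-fold (Pah −4.11, Oat −3.31, Cbs −2.47; camera adjusted p = 5.4e-29). Gluconeogenesis had 21 of 24 lower and none higher, the same adjusted over the list alone (Fbp1 22.0-fold, Gpt −2.33, Got1 −1.99; camera adjusted p = 2e-11). Interferon genes had 39 of 40 higher, also adjusted over the list alone, at a median of 80.2-fold (Isg15 8.11; camera adjusted p = 3.6e-200). Drug and bile acid metabolism had 23 of 35 lower (23 adjusted over the list alone) and Cyp4a14 higher (Baat −3.57; camera adjusted p = 4e-08), fatty acid synthesis 16 of 24 lower and 6 higher, the same adjusted over the list alone (Elovl6 −2.14, Thrsp 3.25; camera adjusted p = 0.0042), and glucagon receptor signalling 18 of 35 lower and 6 higher (19 and 6 adjusted over the list alone; Rapgef4 −2.71, Pygl −1.39; camera adjusted p = 0.0071). These 6 lists kept their call with an estimated correlation and no other did. Fatty acid oxidation had 30 of 32 lower, also adjusted over the list alone (Acsl1 −2.28, Acox1 −1.49), and Vnn1 rose. Here camera gave adjusted p = 3.3e-14, or 0.077 with an estimated correlation. The tricarboxylic acid cycle had 19 of 22 lower, also adjusted over the list alone (Fh1 −1.64, Idh3a −1.44). Camera testing gave adjusted p = 1.6e-05, or 0.090 with an estimated correlation. Oxidative phosphorylation had 51 of 77 lower and none higher (52 adjusted over the list alone; Ndufs1 −0.85, Atp5g1 −0.85). With camera this gave adjusted p = 2.6e-04, and adjusted p = 0.35 with an estimated correlation. All 13 mitochondrially encoded RNAs fell, also adjusted over the list alone, at a median of 6.64-fold. Camera here gave adjusted p = 4.5e-05, and adjusted p = 0.35 with an estimated correlation.

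Hepatocyte identity had 23 of 33 genes lower and 4 higher under glucagon (24 and 5 adjusted over the list alone; Hnf4a −1.89). The camera test gave adjusted p = 4.5e-05, or 0.23 with an estimated correlation. The p53 targets had 19 of 24 higher and Plk3 and Ei24 lower (20 and 3 adjusted over the list alone; Btg2 2.08). Camera gave adjusted p = 1.8e-05, or 0.21 with an estimated correlation. Dedifferentiation genes had 22 of 33 higher (24 adjusted over the list alone; Ccn2 1.88, Ccn1 1.61, Vim 1.22), and Tuba1a, Anxa5 and Sox4 fell. Here camera gave adjusted p = 0.0019, or 0.44 with an estimated correlation. NRF2 targets had 20 of 29 lower (20 adjusted over the list alone; Gsta2 −3.64). Camera then gave adjusted p = 2.6e-04, or 0.14 with an estimated correlation. Male-biased genes had 14 of 19 lower (14 adjusted over the list alone; Cyp2d9 −3.58). By camera this gave adjusted p = 0.0015, or 0.25 with an estimated correlation. Female-biased genes had 14 of 26 lower (14 adjusted over the list alone; Cyp17a1 −4.55). Camera gave adjusted p = 0.0019, or 0.29 with an estimated correlation. Androgen-responsive genes had 15 of 22 lower (15 adjusted over the list alone) and Pmepa1 (1.06) and Hpgd (1.03) higher (Sgk1 −1.07). Camera then gave adjusted p = 0.021, and adjusted p = 0.089 with an estimated correlation. The cAMP list had 15 of 32 lower and 8 higher (16 and 8 adjusted over the list alone; Creb3l3 −3.42; camera adjusted p = 0.039; adjusted p = 0.41 with an estimated correlation), a call that ended with robust empirical Bayes (0.0579) and without the scrambled libraries lowest in mitochondrial transcripts (0.0834). Without a camera call, rises and falls numbered 5 and 13 of 25 for PGC1 and ERR regulators (Sirt3 −1.99; adjusted p = 0.064), 7 and 9 of 26 in cholesterol synthesis (Insig1 1.39; 0.66), 18 and 11 of 34 in the stress response (Ppp1r15a 1.36; 0.22), 3 and 2 of 33 for the cell cycle (Ccnd1 0.96; 0.96), 10 and 13 of 29 in the acute phase list (Il1rn 5.46; 0.70, median −0.10, mean 0.14) and 8 and 9 of 21 for the clock (Per2 2.04; 0.84, median −0.32, mean 0.02). Kupffer markers had 5 and 6 of 18 (Cybb 2.23, Cd68 1.88; 0.84, median −0.43, mean −0.08, against an upward test), endothelial markers 2 and 11 of 18 (Flt4 3.53; 0.22), stellate markers 2 and 1 of 17 (Tagln 1.38; 0.85) and cholangiocyte markers 3 and 0 of 9 (Cldn4 2.57; 0.52). Adjusted over the list alone, rises and falls became 7 and 10 for cholesterol synthesis, 18 and 12 for the stress response, 3 and 1 for the cell cycle, 8 and 10 for the clock and 2 and 12 for endothelial markers. Ccl5 and Lck (2.92) rose among the 4 lymphocyte markers.

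Whether Ar shRNA changed the response to glucagon was tested as the difference of both glucagon effects. Oat rose from 10.5 to 158 CPM with glucagon in scrambled cells and stood at 15.9 and 16.0 CPM in Ar shRNA cells, a difference of −3.90 ± 0.19 on the log2 scale (n = 3 per group, adjusted p = 4.16e-07). Responses were also smaller for Ppargc1a (−1.87 ± 0.26, adjusted p = 0.00107), Esrra (−0.95 ± 0.14, adjusted p = 0.00138), Got1 (−2.30, from 114 to 1689 CPM against 141 to 425 CPM), Sgk1 (−2.41, from 154 to 990 CPM against 388 to 471 CPM) and Slc25a25 (−1.98), and the difference was −1.67 for the glycolytic enzyme Pfkp. No difference was called for Pck1 (−0.31, adjusted p = 0.638), G6pc (−1.14, 0.283), Tat (−1.15, 0.0614), Gcgr (0.30, 0.654), Hmgcs2 (−0.30, 0.855), Fkbp5 (0.44, 0.113) or Ar (−0.18, 0.939). More positive effects with Ar shRNA were those of the hypoxia factor Epas1 (1.34 ± 0.11, adjusted p = 1.39e-05; 108 to 69.4 CPM in scrambled and 41.7 to 67.6 CPM in Ar shRNA cells), Per2 (1.21; 29.3 to 19.3 against 52.2 to 79.8 CPM), Rtp4 (1.25), Pik3ap1 (1.16) and the actin-binding Svil (0.82). Cpt1a differed by −0.56 (adjusted p = 0.0182), a call that ended without scrambled glucagon replicate 2 (0.0505), without Ar shRNA glucagon replicate 1 (0.053), and without the scrambled libraries lowest in mitochondrial transcripts (0.0796).

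Glucagon effects differed for 690 of 14415 genes (4.79%), 276 more positive and 414 more negative with Ar shRNA, and 69 and 136 of them differed at least 2-fold. The DESeq2 Wald test called 1054, 497 more positive and 557 more negative. Of 238 genes that glucagon raised at least 2-fold on average over both arms, 194 (81.5%) had the smaller response with Ar shRNA, with median log2 responses of 1.99 and 1.06 and a median difference of −0.90 (limma fry, adjusted p = 1.58e-04). Single tests called 81 of them smaller and 3 larger. Of 122 genes that glucagon lowered, 113 (92.6%) had the smaller response with Ar shRNA, with medians of −1.69 and −0.83 and a median difference of 0.91 (limma fry, adjusted p = 2.83e-04), 24 called smaller and 0 larger by the edgeR quasi-likelihood test. With sets chosen on the Ar shRNA arm alone, which favours a large response in that arm, the median difference was −0.30 for 109 raised genes (limma fry, adjusted p = 0.044) and 0.28 for 19 lowered genes, where the call ended (limma fry, adjusted p = 0.361). Across genes, which are not independent replicates, the glucagon effects of both arms correlated with r = 0.451 (Spearman 0.442), and 478 genes were called in both, 472 of them in the same direction. Of these, 315 were higher and 157 lower in both, where independent lists would share 48.4 and 20.9. The Ar shRNA effects without and with glucagon correlated across genes with r = 0.894 (Spearman 0.843), with 6295 genes called in both, 3161 higher and 3079 lower in both, where independent lists would share 1050 and 1060. Neither correlation rested on shared libraries. With no filter on low counts, the correlations across genes were 0.0902 for the glucagon effects and 0.499 for the Ar shRNA effects.

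**Figure D3:**
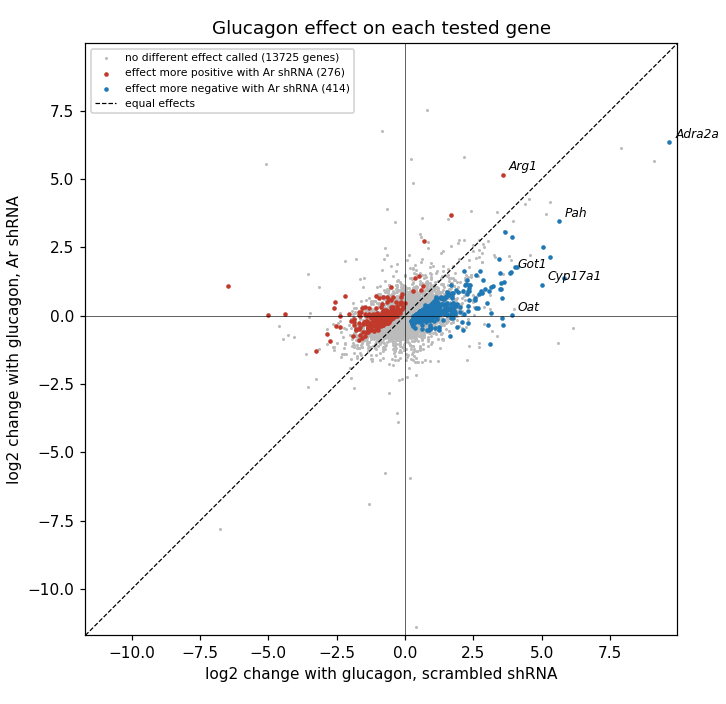
Log2 fold change with glucagon in scrambled cells (horizontal axis) and in Ar shRNA cells (vertical axis) for 14415 genes; red points are the 276 genes with a more positive and blue points the 414 with a more negative effect with Ar shRNA, and the dashed line marks equal effects. Genes with a group at 0 counts are drawn at fitted values, which are not bounds.

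Amino acid catabolism had 21 of 38 genes with a more negative glucagon effect in Ar shRNA cells and Arg1 (1.58) and Gpt2 (1.03) with a more positive effect (26 and 3 adjusted over the list alone), with Ass1 at −2.34 and Pah at −2.17 (median −0.67, camera adjusted p = 4.3e-41). Gluconeogenesis had 6 of 24 more negative and Gpt2 more positive (11 and 1 adjusted over the list alone), with Fbp1 at −2.18 (median −0.31, camera adjusted p = 1.8e-12). Those calls, and no others, held with an estimated correlation. The cAMP list had 5 of 32 more negative and 2 more positive (13 and 4 adjusted over the list alone), with Rgs2 at −2.27, Nr4a1 at −1.25 and Junb at 0.98 (median −0.46). By camera this gave adjusted p = 9.5e-05, or 0.16 with an estimated correlation. Fatty acid oxidation had 7 of 32 more negative (16, and 2 more positive, adjusted over the list alone), with Acsl1 at −0.93 and Eci2 at −0.73 (median −0.32). Camera testing gave adjusted p = 2.7e-08, or 0.16 with an estimated correlation. In the tricarboxylic acid cycle Fh1 (−1.06), Idh3a (−0.81), Mdh2 (−0.74) and Sdhd (−0.55) were more negative of 22, 7 adjusted over the list alone (median −0.23). With camera this gave adjusted p = 4.3e-07, or 0.11 with an estimated correlation. Oxidative phosphorylation had 2 of 77 (1 adjusted over the list alone), Sdhd and Ndufs1, at a median of −0.16. Camera here gave adjusted p = 2.8e-05, and adjusted p = 0.27 with an estimated correlation. Ndufs1 (−0.45) lost its call without scrambled vehicle replicates 2 (0.11) or 3 (0.0948), scrambled glucagon replicates 2 (0.0824) or 3 (0.0979), Ar shRNA vehicle replicates 1 (0.0998) or 2 (0.104), or Ar shRNA glucagon replicates 2 (0.0835) or 3 (0.105), and with DESeq2 size factors (0.0505). PGC1 and ERR regulators had 5 of 25 more negative, also adjusted over the list alone, including Ppargc1a, Esrra and Sirt3 (−0.72; median −0.13). The camera test gave adjusted p = 8e-04, and adjusted p = 0.25 with an estimated correlation. In glucagon receptor signalling 4 of 35 were more negative (5 adjusted over the list alone), with Adcy9 at −0.88 and Pde3b at −0.67 (median −0.12). Here camera gave adjusted p = 0.0098, and adjusted p = 0.10 with an estimated correlation.

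The glucagon effect was more positive in Ar shRNA cells for 9 of 33 dedifferentiation genes (18 adjusted over the list alone; Ccn1 1.04, Actb 0.76, Vim 0.75; median 0.48). Camera testing gave adjusted p = 3.8e-13, and adjusted p = 0.12 with an estimated correlation. It was more positive for 16 of 40 interferon genes and more negative for Usp18 (21 and 1 adjusted over the list alone; Ifit3 1.35, Ifi47 1.10, Irf9 0.81; median 0.49). With camera this gave adjusted p = 3.5e-15, and adjusted p = 0.12 with an estimated correlation. NRF2 targets had Gclc (0.63) and Hmox1 (0.83) of 29, the same adjusted over the list alone. Camera gave adjusted p = 2.9e-05, and adjusted p = 0.12 with an estimated correlation. The acute phase list had 2 of 29, 5 adjusted over the list alone (Socs3 0.94). Camera here gave adjusted p = 3.2e-04, and adjusted p = 0.13 with an estimated correlation. Cholesterol synthesis had Hmgcs1 (0.93) and Insig1 (0.74) of 26, 7 and 2 adjusted over the list alone. The camera test gave adjusted p = 9.4e-04, and adjusted p = 0.23 with an estimated correlation. The p53 targets had Plk2 more positive and Plk3 and Ei24 more negative of 24, 3 and 2 adjusted over the list alone (median 0.19, camera adjusted p = 0.019; adjusted p = 0.50 with an estimated correlation); the call ended without scrambled vehicle replicate 1 (0.073), scrambled glucagon replicate 2 (0.0624), Ar shRNA vehicle replicate 2 (0.0802) or Ar shRNA glucagon replicate 1 (0.0855), and without the scrambled libraries lowest in mitochondrial transcripts (0.0837). The cell cycle list had a median of 0.31 with 0 of 33 genes called by the edgeR quasi-likelihood test (camera adjusted p = 0.023; adjusted p = 0.69 with an estimated correlation), and its call ended without scrambled vehicle replicate 2 (0.0752), scrambled glucagon replicate 1 (0.22), Ar shRNA vehicle replicate 1 (0.566) or Ar shRNA glucagon replicate 2 (0.458). No camera call was made for mitochondrially encoded RNAs (median 0.03, adjusted p = 0.88), fatty acid synthesis (0.93, median −0.07, mean 0.04), androgen-responsive genes (0.11), male-biased genes (0.67), female-biased genes (Cyp17a1 −3.88; 0.079), the stress response (0.75, median 0.07, mean −0.02), drug and bile acid metabolism (Por −0.89; 0.46), the clock (0.11) or hepatocyte identity (Hnf4a −0.73; 0.57). Nor was one made for markers of Kupffer cells (Cd14 0.79; 0.18), endothelium (0.67), stellate cells (0.79) or cholangiocytes (0.082), and none of the 4 lymphocyte markers differed. In these lists more positive and more negative effects numbered 2 and 3 in fatty acid synthesis (4 and 3 adjusted over the list alone), 0 and 2 for androgen-responsive genes (4 and 3), 0 and 0 for male-biased (0 and 1), 1 and 2 for female-biased (3 and 3), 1 and 2 in the stress response (2 and 2), 0 and 1 in drug and bile acid metabolism (2 and 3), 2 and 1 for the clock (4 and 2), 0 and 1 for hepatocyte identity (0 and 2) and 1 and 0 for Kupffer markers.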

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

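Of the tests in this part, the splits of 6 libraries, the reassigned shRNA labels and the limit on low counts were written before their results were seen, and all others were chosen after. No test of single outlying libraries was run. Scrambled vehicle replicate 1 stood at 34.12 on the third principal component, against −18.15 and −19.74 for replicates 2 and 3, and had 1.62% mitochondrial counts, against 3.21% and 3.18%. The first and second patterns below are effects of Ar shRNA. Other results stand out because the glucagon effect differed between scrambled and Ar shRNA. It differed for 690 genes, the median difference was −0.903 for the genes glucagon raised and 0.906 for those it lowered, and 13 single genes and 15 lists are given with their values. With sets chosen on the Ar shRNA arm alone, the median differences were −0.296 and 0.282. The call for lowered genes ended (limma fry, adjusted p = 0.361).

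Named genes with a more positive glucagon effect in Ar shRNA cells were Epas1 (1.34), Rtp4 (1.25), Per2 (1.21), Pik3ap1 (1.16) and Svil (0.824). More negative were Oat (−3.90), Sgk1 (−2.41), Got1 (−2.30), Slc25a25 (−1.98), Ppargc1a (−1.87), Pfkp (−1.67), Esrra (−0.952) and Cpt1a (−0.558). List medians of the difference were −0.673 for amino acid catabolism, −0.31 for gluconeogenesis, −0.458 for cAMP and CREB, −0.323 for fatty acid oxidation, −0.225 for the tricarboxylic acid cycle, −0.162 for oxidative phosphorylation, −0.129 for PGC1 and ERR regulators and −0.119 for glucagon receptor signalling. They were 0.491 for interferon, 0.48 for dedifferentiation, 0.306 for the cell cycle, 0.284 for the acute phase, 0.265 for NRF2 targets, 0.194 for p53 targets and 0.171 for cholesterol synthesis. Only amino acid catabolism and gluconeogenesis kept their camera call with an estimated correlation (adjusted p = 0.017 for both). Both lists hold Got1, Gpt and Gpt2. The others had, with an estimated correlation and in the order given, adjusted p = 0.16, 0.16, 0.11, 0.27, 0.25 and 0.10 for the negative medians and 0.12, 0.12, 0.69, 0.13, 0.12, 0.50 and 0.23 for the positive ones.

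The first pattern is the rise of interferon-response genes in every Ar shRNA library. Macrophages carried into these cultures would raise their markers, whose median log2 change without glucagon was −0.417 (bootstrap interval −1.2 to 0.367), with Lyz2 at −3.32 and Cybb at 2.58. Whether the rise follows the Ar shRNA virus or preparation, or the loss of Ar, cannot be told apart, because 0 libraries had a low Ar level without that virus, or the virus with Ar in the scrambled range. A second shRNA against Ar, or Ar restored, would part them.

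The second pattern is the fall of amino acid catabolism genes with Ar shRNA. Without glucagon 30 of 38 fell and 5 rose, a call that ended at adjusted p = 0.13 with an estimated correlation, and with glucagon all 38 fell, at adjusted p = 0.031 with an estimated correlation. Counts taken up by interferon genes lowered the share of all others by a log2 change of only −0.0433, against a list median of −1.10. The fitted trend on transcript length was at most 0.0685 in size (log2) at the length of any list member. Fewer hepatocytes would raise the markers of other liver cells together. Of the called ones, 58.1% were lower (18 of 31, exact 95% interval 39.1 to 75.5 if markers are independent). Of the 25 called with every library left out in turn, 14 were lower (56%, 34.9 to 75.6). Loss of Ar, the interferon state, the virus and, without glucagon, the 0 h vehicle titles remain open, none tested apart.

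The third pattern is the smaller glucagon response. Ar shRNA libraries did not scatter more (ratio of the median standard deviations 0.906). Over the 127 raised genes with a mean of at least 10 CPM the median difference was −0.823 (bootstrap over genes, −0.981 to −0.66). G6pc passed with 16 to 33 counts per Ar shRNA vehicle library, so a floor in that arm stays open. Of the raised genes, 30.3% departed from 1 common ratio of 0.53, with Pck1, Arg1, Cps1, Adh1 and Mat1a above it and Oat, Ass1, Got1 and Sgk1 below it. Whether 1 weaker signal reached all genes cannot be told apart from separate changes, because genes with different dose responses would depart as well, and 3 of 238 were called larger by the edgeR quasi-likelihood test. Lower Gcgr (−3.20 without glucagon), the interferon state, loss of Ar and the 0 h of Ar shRNA vehicle titles may contribute. None was tested alone.

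Chance was examined with other groupings. For each comparison of a pair of groups, 10 splits of 6 libraries are too few for a share under 0.05. The real splits called 3577, 545, 7452 and 8145 genes and the highest other 0 in each by the edgeR quasi-likelihood test, so 1 split in each gave as many; for glucagon with Ar shRNA, splits that part as many pairs also called 0. With the shRNA labels reassigned within each treatment (100 splits drawn), 8 splits called at least 690 genes (highest other 9352), 15 gave a median difference of raised genes of at least 0.9029 in size (highest other 2.237), and 17 at least 0.9058 in size for lowered genes (highest other 1.561). Sizes were counted because all 100 splits turned sign with the arms exchanged. In the direction named in advance, with the arms as drawn, 7 reached −0.9029 (lowest other −1.654) and 8 reached 0.9058 (highest other 1.115). Chance was not excluded by this test. The 7 other splits with at least 690 calls put unequal numbers of scrambled libraries in the treatments, so the shRNA effect enters the difference. In the 28 others with equal numbers, each group held both shRNAs, which widened its spread, so the highest count, 0 by edgeR, decides nothing. The largest median difference in size was 0.448 for raised and 0.9796 for lowered genes. After the main shRNA and glucagon effects were removed, 1 of 100 reassignments of the residuals, the real one, reached each real value: 709 limma calls (highest other 105), and, in size, 0.8888 for raised genes (0.7496) and 0.8049 for lowered genes (0.6984).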

How the results depend on the processing

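All alternatives were planned, except those given above as added after the data were seen. No called result reversed its direction. Counts of called genes stayed within 1.5 times of those reported under DESeq2 size factors (3577, 544, 7449, 8172 and 691 for glucagon with scrambled and with Ar shRNA, Ar shRNA without and with glucagon, and the difference), unrounded counts (3578, 549, 7449, 8149 and 689), robust empirical Bayes (3561, 556, 7429, 8112 and 724) and no filter on low counts (3313, 573, 7259, 7945 and 794). Without the low-mitochondrial libraries they were 2779, 6996, 7722 and 577 where those libraries enter. The DESeq2 Wald test called 1054 genes for the difference, against 690, and 682 genes were called by both tools; the cause was not tested. With no filter on low counts the correlations across genes fell to 0.09024 for glucagon and 0.4987 for Ar shRNA, because genes with few counts entered them. With an estimated correlation, which also leaves fewer degrees of freedom, 4, 5, 4, 6 and 2 lists kept their call in the 5 comparisons. With a replicate block glucagon changed 895 genes with Ar shRNA, and 2075 with the block and only those 6 libraries, as given beside that result; it changed no call there beyond those given, and no gene of a list lost its call. In the other comparisons, and in the difference, which also uses the scrambled libraries, samples share only a number (own-number correlations as low as 0.0054, 0.011 and −0.02, and 3, 4 and 4 of 6 samples best with their own number): the replicate block moved the difference from 690 to 1221 and gave 4363, 8133 and 8739 for the rest, and the oxidative phosphorylation list lost its call with Ar shRNA on vehicle (adjusted p = 0.0513). Response sets chosen on the scrambled arm gave median differences of −1.02 and 0.92, and on the Ar shRNA arm −0.296 for raised and 0.2823 for lowered genes, the latter no longer past the fry test; choosing on 1 arm favours a large response in that arm. With each library left out in turn, counts ranged over 2727 to 3356, 288 to 394, 6676 to 6987, 7446 to 7688 and 469 to 776, called lists over 15 to 18, 8 to 10, 14 to 17, 19 to 20 and 15 to 16, the correlations over 0.339 to 0.4457 and 0.8361 to 0.8756 (both lowest without scrambled vehicle replicate 1), and the median differences over −1.02 to −0.6801 (highest unadjusted fry p = 5.32e-04) and 0.7254 to 1.014 (0.00134). Fewer libraries leave fewer degrees of freedom. Of the named and called genes, 5 of 110, 23 of 67, 6 of 126, 0 of 128 and 12 of 67 lost their edgeR call without 1 library. Depth limits genes with few counts, such as Ar at 9 to 41 counts per Ar shRNA library.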

Other observations

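The gene groups and genes in this part were chosen after the values were seen. Antigen presentation by MHC class I, which shows peptides to T cells, rose as a group with Ar shRNA: 17 of 17 genes were higher without glucagon (median 2.61, camera adjusted p = 2.3e-41, 0.0015 with an estimated correlation) and 17 of 17 with glucagon (median 2.87, 0.0015 with an estimated correlation). H2-K1 rose from 1700 to 6530 CPM (log2 1.95 ± 0.08, SE, n = 3), H2-D1 by 1.98, B2m by 1.41, the peptide transporter Tap1 by 2.95, the immunoproteasome subunit Psmb9 by 3.08 and the class I regulator Nlrc5 by 2.28. Sensors of foreign DNA and RNA had 11 of 14 higher and 1 lower (median 2.53, adjusted p = 6e-04 with an estimated correlation), with Tlr3 at 4.21 and Zbp1 at 6.91. Genes of inflammatory cell death had 8 of 12 higher (median 1.24, adjusted p = 0.0015 with an estimated correlation), with Casp4 at 3.51, Mlkl at 2.68 and Gsdmd at 1.11, and Nlrp3 stood at −0.08 (adjusted p = 0.926). Interferon beta itself, Ifnb1, had 0 counts in the 6 scrambled libraries and 39, 28 and 25 counts in the 3 Ar shRNA vehicle libraries, 92 in all. With glucagon the counts were 31, 22 and 31, 84 in all. Against a floor of 3 counts over the 6 scrambled libraries, Ifnb1 was at least 59.1-fold higher over the 6 Ar shRNA libraries.

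With Ar shRNA on vehicle, albumin, Alb, the most abundant plasma protein, stood at 15100 and 17300 CPM (log2 0.20, adjusted p = 0.0798), the transthyretin gene Ttr at −0.03 (0.789) and Apoa1 at −0.11 (0.616), whereas Apob fell (−0.98) and plasminogen, Plg, fell (−1.34). Fabp1, a fatty acid carrier of the cytosol, fell as well (−4.65). Complement and coagulation factors had 7 higher and 20 lower of 31 without glucagon (median −0.626, camera adjusted p = 0.0048; adjusted p = 0.25 with an estimated correlation), with Cfb at 1.32, Mbl2 at 1.13 and C3 at −0.38. In scrambled cells glucagon lowered 10 of 17 MHC class I genes (median −0.307, camera adjusted p = 5e-04; adjusted p = 0.36 with an estimated correlation), including Psmb9 (−0.67) and Tap1 (−0.46), and lowered Gsdmd (−0.81) and Zbp1 (−0.81).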
